A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

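The samples were 6 RNA samples of Saccharomyces cerevisiae, 3 labelled wild type (WT) and 3 labelled as a gpm1 knock-out, grown in batch on ethanol and glycerol per the labels' protocols. Per the same protocols, total RNA was released with glass beads, treated with DNase and purified on a column, and part of it was amplified with a kit that primes from the 3' end and labelled with biotin. Each sample was read on 1 one-colour Affymetrix array.

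The authors summarised probes into probe sets with PLIER, per the submitters' processing notes. The deposited values were taken here to be on a log2 scale. The version of PLIER, its settings, any offset added before the log, the scaling between arrays and the base of the log are not given in the sources used here. Base 2 was taken from the range of the values, 4.88 to 13.1, and every fold printed rests on it. An offset, if one was added, makes the folds of dim probe sets smaller than they were. The medians over all probe sets were 6.43, 6.43 and 6.43 for the arrays labelled WT and 6.41, 6.29 and 6.37 for those labelled gpm1. No arrays held identical values.

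The table held 10928 probe sets. The platform annotation listed 7245, of which 7244 named 1 gene and 1 named several, and the rest were 166 control probe sets and 3517 others that are unnamed here. Gene IDs of 5498 listed probe sets were found in the S. cerevisiae gene table of assembly R64, which was used for names only, and 12 symbols were updated through it. The gene IDs of 1747 listed probe sets were not in that table. They were used as background, and their organism was not taken from any source used here. For each gene the probe set with the highest mean over the 6 arrays was kept, a choice that mattered for 47 genes with more than 1 probe set, which left 5449 genes. Probe sets with names ending in _s_at or _x_at can bind more than 1 transcript. The files name no genome build, so no coordinates are given.

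The main comparison was labelled gpm1 minus labelled WT with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, two-sided, on the values as deposited, with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05. A limit of 2-fold, a log2 difference of 1, was counted as well. Shifts of 25 gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 25 lists. Calls within a list were counted over all genes and adjusted over the list alone. The groups, the main test, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. Genes named were GPM1 and its neighbours, the 8 genes highest and the 8 lowest in log2 difference among those past the threshold with groups that did not overlap, and from each list the 2 members with the largest difference among those past the threshold, or the 1 with the smallest p where none passed. Members of the lists for lower glycolysis, serine and glycine metabolism, glycerol metabolism, and gluconeogenesis and the glyoxylate cycle were open to naming.

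The alternative settings chosen then were quantile normalization, centring each array, offsets of 16 and 64, leaving out the dimmest 20% of genes, averaging the probe sets of a gene, testing all yeast probe sets, eBayes with a trend and robust prior, the replicate number as a block, leaving out each array in turn, and, for the lists, an estimated correlation, fry and ranks. The filter on dim genes took the lowest 20% because the annotation names no organism for the other probe sets. Array weights and a filter at the 95th percentile of the background probe sets were chosen after seeing the data.

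The gene test was tested on simulated values for this comparison, over 5449 genes of which 200 were changed. With each gene's moderated SD in each group it recovered 87% of the genes changed by a log2 of 1. It recovered 99% of those changed by a log2 of 2. Of its calls 9.27% were false, a share above the adjusted p threshold. The simulated spread was set gene by gene, which leaves out a departure of an array shared by many genes. In the data 44 genes passed with labelled gpm1 replicate 3 and 2240 without it. The recovered shares therefore do not give the power of the test on these arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.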

Results

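Gene expression was measured in the budding yeast Saccharomyces cerevisiae with 6 one-colour Affymetrix arrays, of which 3 were labelled wild type (WT) and 3 were labelled gpm1, a knock-out of the gene for the glycolytic enzyme phosphoglycerate mutase. By their labels, all cultures were batch cultures on ethanol and glycerol. Each array gave a log2 value for 10928 probe sets, and 5449 yeast genes were tested, each by 1 probe set. The precision of every comparison is limited by the 3 arrays per group. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Probe sets whose gene ID was absent from the S. cerevisiae R64 gene table served as a measure of background. Their median was 5.12 and their 95th percentile 6.10 on the log2 scale, and 5095 of the 5449 genes (93.5%) had a mean above that percentile.

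The first question was whether the deleted gene was absent from the knock-out arrays. GPM1 (YKL152C) encodes the phosphoglycerate mutase that interconverts 3-phosphoglycerate and 2-phosphoglycerate. Its signal ran against the labels on all 6 arrays. It was 5.16, 5.12 and 5.17 on the arrays labelled WT, with a mean of 5.15 ± 0.02 (SD, n = 3), which lay under the background percentile. It was 12.5, 12.5 and 11.8 on the arrays labelled gpm1, with a mean of 12.3 ± 0.39 (SD, n = 3). The log2 difference, labelled gpm1 minus labelled WT, was 7.12 (SE 0.20, limma adjusted p = 8.1e-05), a measured fold of 139. With the dim group set to the background percentile the level was at least 72.1-fold higher in the arrays labelled gpm1. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow. Because the deleted gene goes against the labels, groups are named below only by their labels, and every direction is that of the labelled groups, not of the genotype. The annotation paired no probe set with the chromosomal neighbours YKL151C and YKL153W, which were not analysed here.

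**Figure D1:**
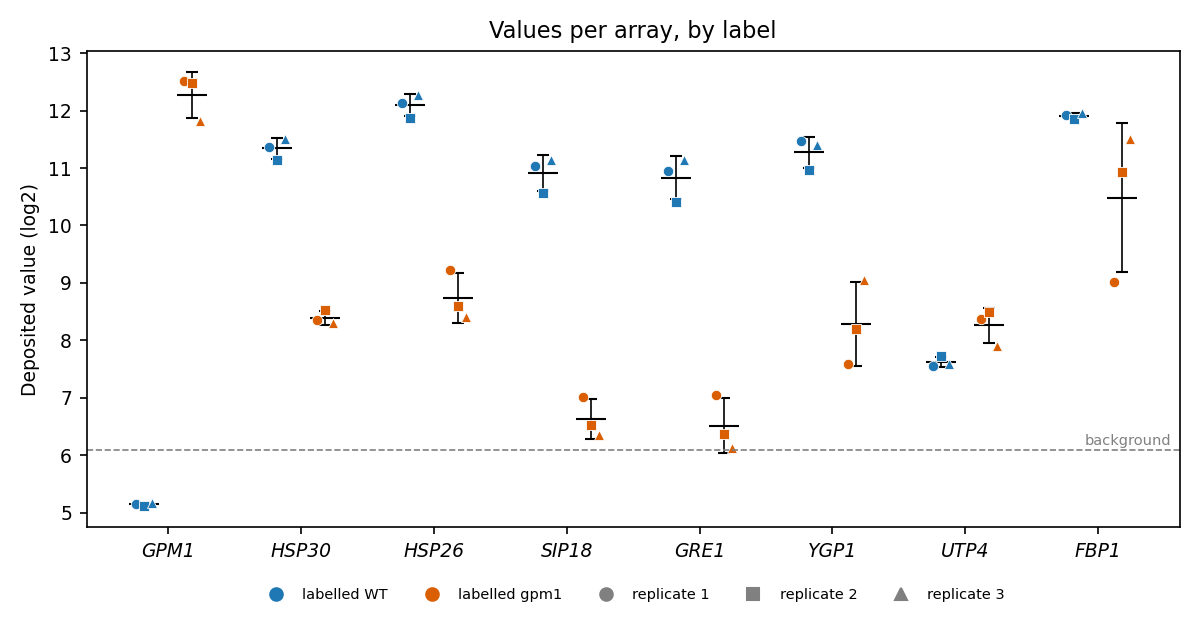
Deposited log2 value (vertical axis) of 8 named genes on each array, with arrays labelled WT in blue and arrays labelled gpm1 in orange, symbols for the replicate number, and black bars for the mean and SD (n = 3). The dashed line is the background percentile of 6.10; GPM1 lies under it on the 3 arrays labelled WT and near 12 on the 3 arrays labelled gpm1.

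The arrays labelled gpm1 differed among themselves far more than those labelled WT. The median SD over genes was 0.248 among the arrays labelled gpm1 and 0.0484 among those labelled WT, a ratio of 5.12. Against the mean of the arrays labelled WT, labelled gpm1 replicate 1 had 270 genes at least 2-fold higher and 356 at least 2-fold lower, and replicate 2 had 164 and 216. Labelled gpm1 replicate 3 had 1 higher gene, GPM1, and 51 lower. The first principal component held 73.8% of the variance. It placed the arrays labelled WT at -15.9, -14.6 and -15.7, labelled gpm1 replicates 1 and 2 at 33.3 and 20.1, and replicate 3 at -7.29. The poly-A control transcripts, which report on RNA handling before labelling, had a mean of 5.92, 6.22 and 6.22 on the arrays labelled WT and of 7.14, 6.67 and 6.21 on labelled gpm1 replicates 1, 2 and 3.

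The next question was which genes differed between the labelled groups. Apart from GPM1, the genes past the threshold were lower in the arrays labelled gpm1, with SIP18 and GRE1 of the stationary phase list and HSP26 and HSP30 of the stress response list among the largest differences. SIP18 and GRE1, which encode hydrophilins (small hydrophilic proteins made under water loss), were lower by 19.5-fold and 19.9-fold. For SIP18 the log2 difference was -4.28 (SE 0.23, adjusted p = 0.0012), and for GRE1 it was -4.32 (SE 0.29, adjusted p = 0.0029). HSP26, a small heat shock protein gene, was 10.3-fold lower at -3.36 (SE 0.23, adjusted p = 0.0029). HSP30, which encodes a heat shock protein of the plasma membrane, was 7.70-fold lower at -2.94 (SE 0.13, adjusted p = 0.00070). The others of the 8 largest falls were FMP16 at -3.33, the cell wall protein gene PIR3 at -2.87 and the plasma membrane protein gene FMP45 at -2.85, and YGP1, for a secreted glycoprotein, which was 7.99-fold lower (SE 0.37 on the log2 scale), with adjusted p-values between 0.0028 and 0.027. All 3 arrays labelled gpm1 lay under all 3 labelled WT for each of these 8 genes, as the rule for naming them required.

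In all, 44 genes passed an adjusted p of 0.05 with limma. GPM1 was the only one higher in the arrays labelled gpm1, and 43 were lower. A difference of at least 2-fold was reached by 37, of which 36 were lower. At an unadjusted p under 0.05 there were 1223 genes. The groups did not overlap for 1885 genes (34.6%), where chance gives 10% for a single gene. Genes are not independent, so the share over all genes can lie far from 10% without a group effect. Other groupings of the arrays were not compared for this share. Of the 43 lower genes, 20 belonged to a gene list fixed beforehand and 16 of these to the stress response or stationary phase lists. The count depended on single arrays. Without labelled gpm1 replicate 3 it was 2240, with 1176 higher and 1064 lower, all 43 lower genes among them, and 402 reached 2-fold (172 higher, 230 lower). With 2240 of 5449 genes past the threshold in that fit, a pass there does not by itself set a gene apart. The count was 11 without labelled WT replicate 1, 19 without labelled WT replicate 2, 13 without labelled WT replicate 3 and 12 without labelled gpm1 replicate 2, and in each of these 4 settings every called gene reached 2-fold. Without labelled gpm1 replicate 1 it was 60, with 2 higher and 58 lower, and 32 of the 44 genes kept their call. The fit takes 1 spread per gene for both labelled groups and has less to estimate it from when an array is left out. A call lost there need not mean a lost difference. YGP1 lost its call without any 1 of the arrays labelled WT and without labelled gpm1 replicate 2. Its limma adjusted p-values over the alternatives ranged from 0.00096 to 0.195. With 1 array left out, its log2 difference stayed between -3.38 and -2.65.

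**Figure D2:**
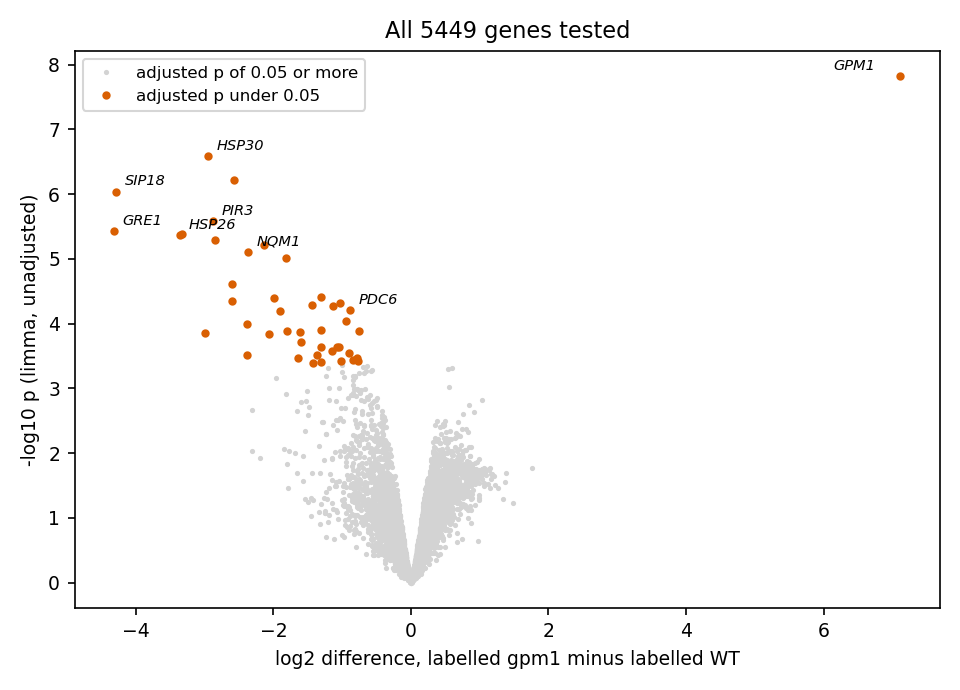
Log2 difference, labelled gpm1 minus labelled WT (horizontal axis), against the -log10 of the unadjusted limma p (vertical axis) for each of the 5449 genes. Orange points are the 44 genes with an adjusted p under 0.05; GPM1 lies at 7.12 on the right, and the other 43 lie on the left.

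The medians of the general stress response and stationary phase lists lay below labelled WT in each of the 3 arrays labelled gpm1, with about as many members past the threshold as not. Of 21 measured stress response genes, which encode chaperones and antioxidant enzymes among others, 11 were lower, 0 were higher and 10 did not pass, and 16 were lower when adjusted over the list alone. The median log2 difference of the list was -1.03, and against the mean of the arrays labelled WT it was -1.04, -1.21 and -1.05 in labelled gpm1 replicates 1, 2 and 3. HSP26 and HSP30 had the largest differences in this list. Of 11 stationary phase genes, 5 were lower, 0 were higher and 6 did not pass, and 9 were lower when adjusted over the list alone. The median was -2.31, and -2.41, -2.75 and -2.07 in the 3 arrays. GRE1 and SIP18 led this list. Without labelled gpm1 replicate 3, 9 of its genes were lower and 1 was higher, UBI4 for polyubiquitin at 0.46, a gene named here after its values were seen. Both lists were called lower by camera with a preset correlation of 0.01, at adjusted p = 4.0e-13 for the stress response and 2.5e-09 for stationary phase. Both calls were lost with an estimated correlation (adjusted p = 0.151 for each, the highest of their alternatives, which began at 1.9e-15 and 1.2e-11). Both passed fry, a test of whether a list's genes move one way, at adjusted p = 0.0026.

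Camera called peroxisomal beta-oxidation and trehalose and glycogen metabolism lower, at adjusted p = 9.2e-07 and adjusted p = 2.4e-07. Both calls were lost with an estimated correlation (adjusted p = 0.464 and adjusted p = 0.489, the highest of their alternatives, which began at 4.0e-08 and 2.1e-08), and with fry both stood at adjusted p = 0.042. In peroxisomal beta-oxidation, 1 of 16 genes was lower, the enoyl-CoA isomerase gene ECI1 at -1.14 (SE 0.16, adjusted p = 0.043), and 9 were lower when adjusted over the list alone. The list median was -0.84, and it was -1.34, -1.04 and -0.54 in labelled gpm1 replicates 1, 2 and 3. This is the order of the poly-A controls (7.14, 6.67 and 6.21). It is also the order of the first principal component (33.3, 20.1 and -7.29), so it does not tie the list to the controls. Without labelled gpm1 replicate 3, 9 of the list's genes were lower and 1 was higher. The ECI1 call held without labelled gpm1 replicate 3. It was lost when any other array was left out, when arrays were centred on their median and with the replicate number as a block, with adjusted p-values from 0.00094 to 0.285 over its alternatives. In trehalose and glycogen metabolism, 0 of 17 genes passed over all genes and 12 were lower when adjusted over the list alone. Without labelled gpm1 replicate 3, 13 were lower over all genes. The median was -0.48, and -0.56, -0.68 and -0.34 in the 3 arrays. TPS2, the trehalose phosphatase gene, had the smallest p of that list, at -0.59 (SE 0.09, adjusted p = 0.055), and it passed without labelled gpm1 replicate 3, at -0.62.

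Lists of gluconeogenesis, of ethanol use and of the tricarboxylic acid cycle were also called lower. Their medians lay farthest from labelled WT in labelled gpm1 replicate 1 and nearest to it in replicate 3. The poly-A controls (7.14, 6.67 and 6.21) and the first principal component have that order too, so it does not tie these lists to the controls. In gluconeogenesis and the glyoxylate cycle, 0 of 14 genes passed over all genes, 2 were lower when adjusted over the list alone, and 10 were lower without labelled gpm1 replicate 3. The median was -0.50, and -0.73, -0.66 and -0.06 in the 3 arrays. MDH2, the cytosolic malate dehydrogenase gene, stood at -0.80 (adjusted p = 0.088), and PCK1, for phosphoenolpyruvate carboxykinase, at -0.56 (adjusted p = 0.120). FBP1, for fructose-1,6-bisphosphatase, was 11.9 ± 0.05 on the arrays labelled WT and 10.5 ± 1.30 on those labelled gpm1 (SD, n = 3), which did not pass (limma adjusted p = 0.227). In ethanol and acetate metabolism, 1 of 21 genes was lower, both over all genes and over the list alone. This was PDC6, a minor pyruvate decarboxylase gene, at -0.89 (SE 0.09, adjusted p = 0.017). PDC6 lost its call without any 1 of the arrays labelled WT, without labelled gpm1 replicate 2 and with the replicate number as a block, over a range of 0.0020 to 0.183. The list median was -0.34, and -0.66, -0.37 and -0.08 in the 3 arrays. In the tricarboxylic acid cycle, 0 of 17 genes passed, over the list alone too. The median was -0.25, and -0.54, -0.08 and -0.04 in the 3 arrays, with CIT3, a mitochondrial citrate synthase gene, at -0.84 (adjusted p = 0.162). With labelled gpm1 replicate 3 left out, MDH2 passed at -0.95, PCK1 at -0.66, FBP1 at -1.94 and CIT3 at -1.02. Over their alternatives the limma adjusted p reached 0.476 for MDH2 and 0.506 for PCK1, FBP1 and CIT3. In the fit without replicate 3, 9 ethanol and acetate genes and 3 tricarboxylic acid cycle genes were lower, where 2240 of all 5449 genes passed. The camera adjusted p was 0.0010, 0.0019 and 0.0052 for these 3 lists in turn. With an estimated correlation all 3 calls were lost (adjusted p = 0.564, adjusted p = 0.564 and adjusted p = 0.596, the highest of their alternatives, which began at 0.00013, 0.00055 and 0.00012). The tricarboxylic acid cycle call was also lost without labelled gpm1 replicate 1, at 0.133.

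The pathways on either side of the phosphoglycerate mutase step showed no shift in 1 direction past the threshold by camera with all 6 arrays. In its mixed form, which counts movement either way, fry gave an adjusted p of 0.0064 for upper and 0.064 for lower glycolysis. In upper glycolysis 0 of 12 genes passed over all genes, and over the list alone 1 was higher and 3 were lower (median -0.09, camera adjusted p = 0.237). TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, stood at -1.50 (SE 0.27, adjusted p = 0.080). In lower glycolysis without GPM1, 0 of 6 genes passed over all genes and 1 was lower over the list alone (median -0.26, camera adjusted p = 0.215). ENO1, for an enolase, stood at -1.28 (SE 0.28, adjusted p = 0.140), with values of 9.85, 10.98 and 10.5 on the arrays labelled gpm1 against a mean of 11.7 on those labelled WT. ENO2, for the other enolase, differed by -0.03 (adjusted p = 0.897) and CDC19, for the main pyruvate kinase, by -0.24 (adjusted p = 0.406). The GPM1 homologues GPM2 and GPM3 differed by -0.27 (adjusted p = 0.272) and 0.57 (adjusted p = 0.209). Without labelled gpm1 replicate 3, TDH1 passed at -1.28, ENO1 at -1.31 and GPM3 at 0.73. Without labelled gpm1 replicate 2 both glycolysis lists were called, at 0.0138 for the upper and 0.0441 for the lower, in ranges up to 0.922 and 0.691. The probe sequences were not used here, so signal shared with close copies was not checked for TDH1 and the enolase genes.

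Serine and glycine metabolism branches from 3-phosphoglycerate, and 0 of its 15 genes passed, over the list alone too (median -0.53, mean -0.40, camera adjusted p = 0.139). Its members went both ways. GLY1, for threonine aldolase, stood at -0.80 (adjusted p = 0.171), and SER3, for 3-phosphoglycerate dehydrogenase, at -0.53 (adjusted p = 0.196). SER2, for phosphoserine phosphatase, stood at 0.64 (adjusted p = 0.196). GCV2, for a subunit of glycine decarboxylase, was 7.80, 9.63 and 10.98 on the arrays labelled gpm1 and 10.8 ± 0.07 on those labelled WT (SD, n = 3). AGX1, for alanine-glyoxylate aminotransferase, was 9.28, 11.7 and 11.9 against 11.9 ± 0.02. In glycerol metabolism 0 of 12 genes passed, over the list alone too (median -0.07, camera adjusted p = 0.135). GCY1, for a glycerol dehydrogenase, stood at -0.81 (adjusted p = 0.166). STL1, for a glycerol symporter, was 8.75, 8.79 and 10.1 on the arrays labelled gpm1 against 10.1 ± 0.08 on those labelled WT. The glycerol kinase gene GUT1 was 8.26, 9.71 and 9.90 against 9.72 ± 0.07. GUT2, for the mitochondrial glycerol-3-phosphate dehydrogenase, differed by -0.04 (adjusted p = 0.872). With labelled gpm1 replicate 3 left out, 3 serine and glycine genes passed as higher, SER2 at 0.85, SHM1 at 0.56 and MIS1 at 0.55, and 3 as lower, GLY1 at -0.97, MTD1 at -1.53 and GCV2 at -2.07. Of the glycerol genes 1 passed as higher in that fit, GPD2 at 0.26, and 2 as lower, GCY1 at -1.02 and STL1 at -1.29. As 2240 of all 5449 genes passed in that fit, these counts do not set either list apart.

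Ribosome biogenesis was the 1 list called higher in the arrays labelled gpm1. Over all genes 0 of its 53 members passed, while 41 were higher when adjusted over the list alone and 46 were higher without labelled gpm1 replicate 3. The median was 0.74, and it was 0.98, 1.04 and 0.19 in labelled gpm1 replicates 1, 2 and 3, whose poly-A controls stood at 7.14, 6.67 and 6.21 against at most 6.22 on the arrays labelled WT. UTP4, for a component of the small-subunit processome, had the smallest p of the list at 0.64 (SE 0.17, adjusted p = 0.185). The camera adjusted p was 8.1e-14, and the call was lost with an estimated correlation (adjusted p = 0.564, the highest of its alternatives, which began at 2.7e-22) and with fry (adjusted p = 0.128). Cytosolic ribosomal protein genes had 0 of 127 past the threshold, over the list alone too (median 0.04, mean -0.02, camera direction higher at adjusted p = 0.260), with RPL15B at -0.44 (adjusted p = 0.196), whose near-identical copy RPL15A may share its signal. That list was called without labelled gpm1 replicate 1, at 0.0303, and without replicate 2, at 0.0133, in a range up to 0.820. Without replicate 3, 4 of its genes were higher and 19 lower, and the camera direction was lower at adjusted p = 0.387. Mitochondrial ribosomal protein genes had 0 of 69, over the list alone too (median 0.01, mean -0.01, camera direction higher at adjusted p = 0.556), with MRPL25 at 0.68 (adjusted p = 0.139). Their medians were -0.40, 0.10 and 0.28 in the 3 arrays labelled gpm1, and the list was called higher without replicate 1, at 8.0e-12, in a range up to 0.917. With labelled gpm1 replicate 3 left out, UTP4 passed at 0.81, RPL15B at -0.53 and MRPL25 at 0.80.

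Lists of nitrogen metabolism were called lower with 0 genes past the threshold, over all genes and over the list alone. Amino acid permeases (22 genes) had a median of -0.30 and a camera adjusted p of 0.0023, amino acid biosynthesis (49 genes) -0.30 and 0.0087, and sulfur amino acid metabolism (22 genes) -0.25 and 0.028. With an estimated correlation the calls were lost (adjusted p = 0.564, adjusted p = 0.621 and adjusted p = 0.621, in ranges of 0.00013 to 0.564, 0.00025 to 0.621 and 0.0028 to 0.671 over their alternatives). The calls for amino acid biosynthesis and sulfur amino acid metabolism were also lost without labelled gpm1 replicate 1, at 0.504 and 0.671. The smallest p of each list belonged to UGA4, a permease gene for 4-aminobutyrate, at -0.43 (adjusted p = 0.174), PRO1, for glutamate kinase, at 0.66 (adjusted p = 0.166) and MET32, a regulator of sulfur genes, at -0.48 (adjusted p = 0.181). With labelled gpm1 replicate 3 left out, UGA4 passed at -0.53, PRO1 at 0.83 and MET32 at -0.59. In that fit 9 permease genes were lower. Of the amino acid biosynthesis genes 16 were lower and 5 higher there, and of the sulfur genes 7 were lower and 2 higher. In labelled gpm1 replicates 1, 2 and 3 the median was -0.26, -0.48 and -0.06 for permeases and -0.64, -0.11 and -0.0046 for amino acid biosynthesis. For sulfur amino acid metabolism it was -0.86, -0.20 and 0.04. The biosynthesis and sulfur medians ran in the order of the poly-A controls (7.14, 6.67 and 6.21), which is also that of the first principal component.

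The remaining lists were not called by camera. In the pentose phosphate pathway 2 of 11 genes were lower, NQM1 for a minor transaldolase at -2.37 (SE 0.18, adjusted p = 0.0039) and TKL2 for a minor transketolase at -2.60 (SE 0.26, adjusted p = 0.015). Over the list alone 1 was higher and 3 were lower (median -0.14, camera adjusted p = 0.185). With fry this list was called lower, at adjusted p = 0.0138, in a range of 0.0138 to 0.724 over its alternatives. The TKL2 call was lost without labelled WT replicate 1, labelled WT replicate 3 or labelled gpm1 replicate 2, in a range of 0.0025 to 0.125. Oxidative phosphorylation had 0 of 33 genes past the threshold, over the list alone too (median -0.08, camera adjusted p = 0.135), and was called without labelled gpm1 replicate 2, at 0.0147, in a range up to 0.707. NDE2, for an external NADH dehydrogenase, stood at -1.79 (adjusted p = 0.208), with values of 6.91, 7.06 and 9.46 on the arrays labelled gpm1 against a mean of 9.60 on those labelled WT. It passed without labelled gpm1 replicate 3, at -2.62. Purine biosynthesis had 0 of 13, over the list alone too (median -0.17, camera adjusted p = 0.312), with IMD4 at 0.73 (adjusted p = 0.196). Hexose transporters and sensors had 0 of 17 over all genes and 1 higher over the list alone, HXT2 at 0.92 (adjusted p = 0.114; list median -0.03, camera adjusted p = 0.312). IMD4 and HXT2 also passed without labelled gpm1 replicate 3, at 0.99 and 1.03.

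Markers of cell type gave no call. Genes specific to MATa cells (7 genes) had a median of 0.27 and a camera adjusted p of 0.460, with the alpha-factor receptor gene STE2 at 0.47 (adjusted p = 0.201). Genes specific to MATalpha cells (5 genes) had a median of 0.02, while camera gave the lower direction at 0.728, with the a-factor receptor gene STE3 at -0.21 (adjusted p = 0.219). Haploid-specific genes (9 genes) had a median of 0.15 and 0.392, with RME1, a repressor of meiosis, at -1.15 (adjusted p = 0.196). Meiosis and sporulation genes (19 genes) had a median of -0.04 and 0.129, with 3 lower over the list alone and SPS100, a spore wall gene, at -1.01 (adjusted p = 0.053). RME1 passed at -1.48 and SPS100 at -1.09 without labelled gpm1 replicate 3. SPS100 also passed with a trend and robust prior and with the filter at the background percentile. The meiosis list was called without labelled gpm1 replicate 1, at 0.0189, in a range up to 0.596. Over all genes 0 members of these 4 lists passed, and in the other 3 lists 0 passed over the list alone.

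**Figure D3:**
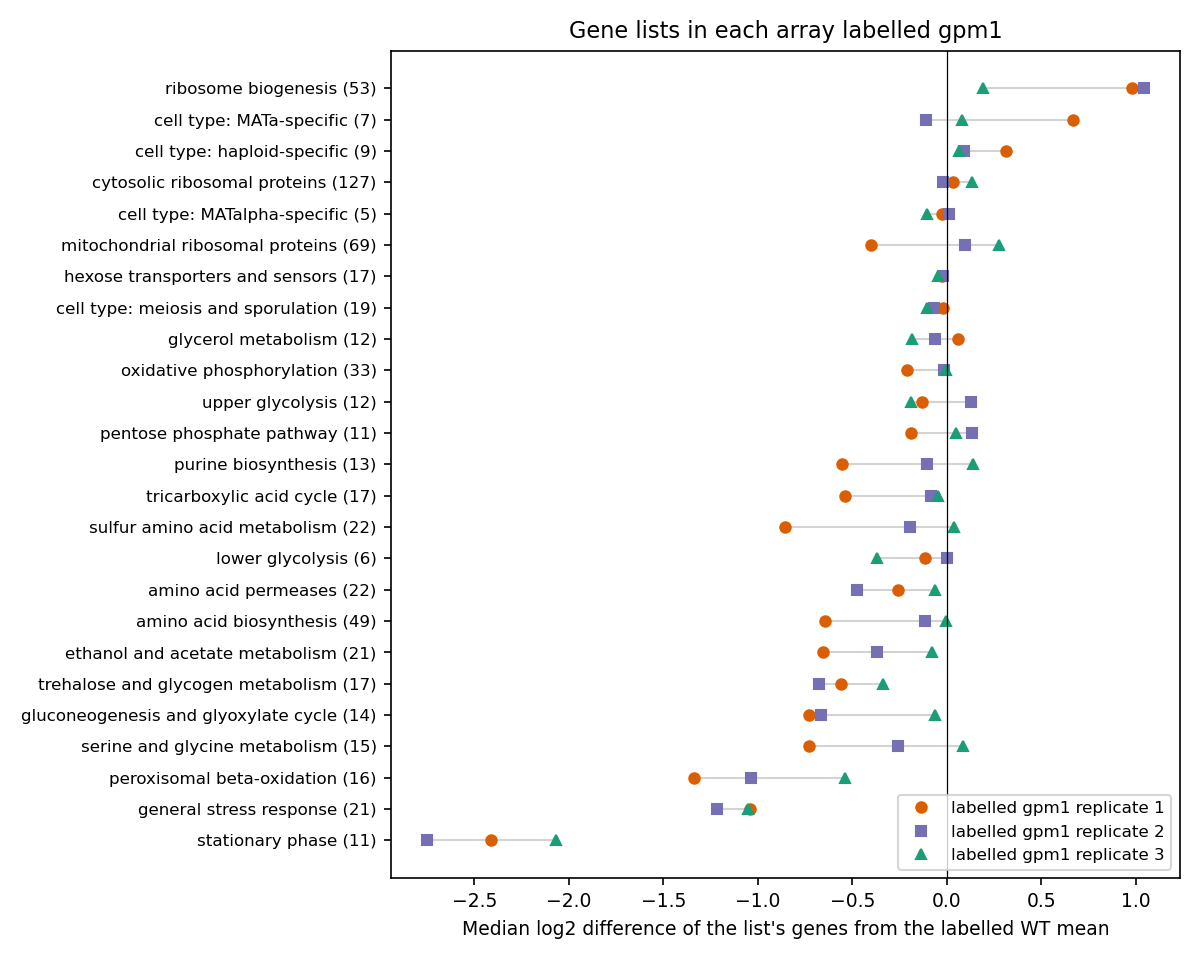
Median log2 difference of each gene list from the mean of the arrays labelled WT (horizontal axis), for labelled gpm1 replicates 1 (circles), 2 (squares) and 3 (triangles), with the number of measured genes in brackets and a grey line over the range. The stress response and stationary phase lists lie below -1 in all 3 arrays; ribosome biogenesis lies near 1 in replicates 1 and 2 and at 0.19 in replicate 3.

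Of the 25 lists, 11 were called by camera, 10 lower and 1 higher. With an estimated correlation 0 of the 11 calls held, the lowest adjusted p being 0.151, and fry called 5 lists. The camera count does not set the labelled groups apart from other groupings, since each of the 9 other ways to split the 6 arrays into 3 and 3 called between 9 and 16 lists.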

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

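The tests of explanations in this part were chosen after the results were seen, except the counts over splits of the arrays, which were planned.

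The GPM1 signal ran against the labels. Arrays labelled WT lay under the background percentile and arrays labelled gpm1 far above it, so 6 of 6 arrays were on the side opposite to their label, as an exchange of the labels of both groups would give; a step at which this may have happened was not tested. Signal from GPM2 or GPM3 on the GPM1 probe set is argued against, because the larger of their differences was 0.57, where GPM1 differed by at least 6.17 over background. A deletion that leaves the probed region in place is argued against by the GPM1 mean of 5.15 on the arrays labelled WT, at background. An error in the pairing of this probe set with GPM1 in the annotation stays open, as probe sequences were not used here.

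Labelled gpm1 replicate 3 lay close to the arrays labelled WT for most genes. Its correlation over genes was 0.977 to 0.984 with the arrays labelled WT and 0.912 to 0.958 with the other arrays labelled gpm1 (genes are not independent replicates). Admixed RNA of a labelled WT culture would place all gene groups at 1 position on the linear scale (2 to the power of the value). Position ran from labelled WT (0) to the mean of the other arrays labelled gpm1 (1). The median position was 0.131 for 46 of 53 ribosome biogenesis genes and 0.939 for 23 of 32 stress and stationary phase genes, with GPM1 at 0.622. The list genes used were those past the threshold in the fit without replicate 3, on the same values that set the scale of the position. The difference between the medians was 0.808 (95% bootstrap interval 0.652 to 0.905). That interval resamples genes of 1 array, so it holds no spread between samples. Both gene groups were picked for this comparison after their medians in replicate 3 had been seen. A labelled WT sample in its place is argued against by its GPM1 value of 11.8. A difference in RNA degradation is argued against by the 3' minus 5' value of 7 control transcripts. It differed from that of replicates 1 and 2 by 0.0756 (SE 0.063 over the transcripts, not over samples). A difference in growth state between the cultures may lie behind the pattern, and it was not tested because the labels give no growth phase or sampling time.

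The stress response and stationary phase lists had medians below labelled WT in all 3 arrays labelled gpm1. A shift of whole arrays left in the deposited values is argued against, since the median difference over all 5449 genes was 0.0192. Scaling between arrays, which is not known here, can bring that median near 0, so a shift that it removed cannot be judged. In labelled gpm1 replicate 3 the poly-A controls lay within the range of the arrays labelled WT. There 31 of the 32 genes of both lists were lower, with a median of -1.05 (95% bootstrap interval -1.88 to -0.59). The interval resamples genes of 1 array, which are not independent, so it holds no spread between samples. As far as 1 array shows, a fall without raised controls argues against RNA input as the source there. In replicates 1 and 2 the median was -1.20 and 27 of 32 were lower, and the controls were raised too. The fall did not follow the order of the controls, which were 7.14, 6.67 and 6.21 in replicates 1, 2 and 3. In that order the stress response median was -1.04, -1.21 and -1.05 and the stationary phase median -2.41, -2.75 and -2.07. A part of RNA input in replicates 1 and 2 still cannot be told apart from a difference between the cultures. The genotype that the labels name stays untested as a cause, since GPM1 goes against the labels.

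The poly-A controls, bacterial transcripts normally added to a sample before labelling, had a mean over 36 probe sets of 7.14 in labelled gpm1 replicate 1 and 6.67 in replicate 2, above the highest array labelled WT at 6.22. Replicate 3 stood at 6.21. Lists such as ribosome biogenesis that moved mainly in replicates 1 and 2 moved with the raised controls, and RNA input was not tested for them. Among the 3517 probe sets unnamed here, 4 differed between the labelled groups by limma, 2 higher and 2 lower in the arrays labelled gpm1, and 261 had an unadjusted p under 0.05. The higher ones differed by 1.17 and 1.06, but both lay under the background percentile of 6.10 on all arrays labelled WT. On the arrays labelled gpm1 they lay near it, at 6.04 to 6.36, so these sizes are not exact. The lower ones differed by -0.53 and -1.04.

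The planned splits are too few for a share under 0.05. The labelled split gave 44 genes and the highest of the others 0, so 1 of the 10 splits gave as many. For genes of at least 2-fold it gave 37 and the highest other 0, again 1 of 10. For gene lists it gave 11 and the highest other 16, and 9 of 10 splits gave as many.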

How the results depend on the processing

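Array weights and the filter at the background percentile were chosen after seeing the data. GPM1 kept its direction and call in all alternatives run, its size being limited by the background level of the arrays labelled WT, and none of the named genes or lists that were called changed sign. The number of genes was 31 to 56 over the other planned settings that keep all arrays, and 45 with the background filter. With array weights it was 1009 (509 higher, 500 lower), with 215 of at least 2-fold, and the cause was not tested. Among named genes not called with all arrays, 35 passed without labelled gpm1 replicate 3 and 32 with array weights, in fits that called 2240 and 1009 of the 5449 genes. Leaving out 1 array gave 11 to 2240 genes, 11 to 402 of at least 2-fold and 11 to 15 lists. No pairing of the arrays by replicate number was seen. Deviations of arrays with the same number correlated at 0.05, 0.02 and -0.13, none best with its own number. The arrays labelled WT deviated little from their mean, so this check cannot exclude handling shared by arrays of 1 number. The fit with the replicate block gave 31 genes, 30 of them among the 44.

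The estimated correlation called 0 lists and fry 5. With the estimated correlation the adjusted p was 0.151 for stress response and stationary phase, 0.464 for peroxisomal beta-oxidation, 0.489 for trehalose and glycogen, 0.564 for ribosome biogenesis, gluconeogenesis and glyoxylate, ethanol and acetate, and amino acid permeases, 0.596 for the tricarboxylic acid cycle, and 0.621 for amino acid biosynthesis and sulfur amino acids. With fry it was 0.128 for ribosome biogenesis and gluconeogenesis and glyoxylate, 0.1004 for ethanol and acetate, 0.222 for amino acid permeases, 0.288 for the tricarboxylic acid cycle, 0.399 for sulfur amino acids, 0.403 for amino acid biosynthesis, and 0.0138, a gain, for the pentose phosphate pathway. Leaving out 1 array gave 0.00025 to 0.504 for amino acid biosynthesis, 0.0028 to 0.671 for sulfur amino acids, 0.00012 to 0.133 for the tricarboxylic acid cycle, 0.0138 to 0.691 for upper and 0.0441 to 0.691 for lower glycolysis, 0.0147 to 0.707 for oxidative phosphorylation, 0.0133 to 0.764 for cytosolic and 8.0e-12 to 0.776 for mitochondrial ribosomal proteins, and 0.0189 to 0.387 for meiosis and sporulation. The cause was not tested for any of these. With the dimmest genes left out the meiosis list had no gene and no value. Of the 43 lower genes, 4 lay under the background percentile on all 3 arrays labelled gpm1, so their folds are limited by background, and 1 of these, YOL131W, was under it on all arrays labelled WT too (named after its values were seen).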

Other observations

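The test in this part was chosen after the arrays had been compared. Genes of auxotrophic markers, which strain construction can alter, did not pass between the labelled groups with all 6 arrays. URA3 differed by -0.29 (limma adjusted p = 0.287), HIS3 by -0.11 (adjusted p = 0.409), LEU2 by -0.45 (adjusted p = 0.527), LYS2 by -0.86 (adjusted p = 0.265) and MET17 by -0.14 (adjusted p = 0.609), labelled gpm1 minus labelled WT. URA3 passed at -0.45 and LYS2 at -1.23 without labelled gpm1 replicate 3. TRP1 was not analysed here.

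A hypothesis that a gained or lost chromosome may underlie the differences between the labelled groups was tested on the median difference of each of 16 chromosomes, in each array labelled gpm1, relative to the median of all its genes. The largest was 0.0884, and the doubling of a chromosome in a haploid would move its median by about a log2 of 1, so the test argues against it.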
